A study of Homo sapiens with 4 samples.

How the data were processed

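Human umbilical vein endothelial cells had been given vehicle or thrombin at 2 U/mL for 2 h, then cycloheximide at 100 ng/mL to hold ribosomes on their messages, per the labels and the design text. Monosome and polysome RNA from sucrose gradients was copied into 33P-labelled cDNA with oligo-dT primers and hybridised to ResGen GF211 nylon filters, which were read by phosphorimaging with the Pathways 3 software, per the labels. The 4 filters were grouped by their titles. The source names of both thrombin samples say vehicle, which conflicts with their titles, and the titles were used. With 1 filter per group there was no p-value, standard error or count adjusted for multiple tests.

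The deposited values are linear spot intensities, made by the authors. The design text says that each signal was divided by the average of its filter, but the deposited intensities have a median of exactly 1 on each filter and means of 2.73 (control monosome), 2.29 (control polysome), 2.40 (thrombin monosome) and 2.39 (thrombin polysome), so their scale is that of the filter median. The brightest 1% of elements, 41 in number, held 38.1%, 25.5%, 34.9% and 26.3% of the signal of these filters, in that order. Whether background was subtracted is not given in the sources used here. The screen for a signal over background above 1.1 that the design text describes was not repeated, since background values were not used here, so dim elements may include some at background level. All 4132 elements had a value above 0 on every filter and were kept.

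Each filter was divided by its mean, the scaling that the design text names. The TS was polysome over monosome, the TLI was the TS with thrombin over the TS in control cells, and the summed ratio was monosome plus polysome signal with thrombin over the same sum in control cells. The TLI formula written with the samples names the same fraction on both sides and runs the other way, so the definition in the design text was used. Elements at or above 2.5 or at or below 0.4 were counted, limits that the design text calls arbitrary. No genome build was used and no coordinates are given.

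Gene names came from the platform's annotation of the elements: 1582 elements had 1 gene, 52 had several and stayed unnamed, and 2498 were unnamed here. Of the named elements, 1580 matched a current gene by identifier, and 0 symbols changed. Genes were named by a rule set before the data were examined: the 12 named elements with the highest and the 12 with the lowest TLI past a limit whose mean normalized signal was above the median and whose call held under median scaling (15 and 8 passed), up to 6 in each direction for the summed ratio by the same rule (3 and 1 passed), and up to 2 of the highest and 2 of the lowest TLI from each of 27 gene lists. Any other name was chosen after its values were seen. Genes that show the sex of a donor were not named.

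For each list with at least 5 measured genes, the median log2 value was set against 10000 random lists of the same size, drawn from genes of matched mean signal. A gene's value was the mean log2 value of its elements. Such percentiles describe these filters and are no test of the treatment. The spread between elements of the same gene was the pooled SD of log2 values, with an interval from 10000 bootstrap draws of genes. The counting was tested on simulated data built on the signals of the 4132 elements with the repeat spread: for the TLI, 32% of 2-fold increases, 84% of 4-fold increases and 96% of 8-fold increases passed the upper limit, and 40%, 92% and 100% of decreases of those sizes passed the lower limit, with 25 elements in each class.

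The alternatives were median scaling, quantile normalization over the 4 filters, an intensity-dependent loess (span 0.3, 3 robustness iterations), elements with a signal above the median only, a pseudocount of 0.1 of the filter mean, limits of 2 and 0.5 and of 4 and 0.25, counts over genes, and the brightest element of each gene. A mean without the brightest 1% of elements was added after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.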

Results

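The data described how strongly messenger RNAs were loaded onto ribosomes in human umbilical vein endothelial cells, the primary cells that line the vein of the umbilical cord, with and without thrombin. Thrombin is the protease of the clotting cascade and activates endothelial cells through G protein-coupled receptors. RNA bound to single ribosomes (monosomes) and RNA bound to several ribosomes (polysomes) was collected from sucrose gradients of vehicle-treated cells and of cells given thrombin at 2 U/mL for 2 h. Labelled cDNA of each fraction was hybridised to its own nylon cDNA filter, so that each of the 4 groups (control monosome, control polysome, thrombin monosome, thrombin polysome) held 1 filter with 4132 elements. There were no replicates, and the number of filters limited the precision of every value. A single gene name was known for 1582 elements, which covered 1532 genes. Log2 signals correlated across elements with a Pearson r of 0.923 between both monosome filters, 0.941 between both polysome filters and 0.858 to 0.864 between a monosome and a polysome filter. Elements are not independent replicates, and these correlations only describe the filters.

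The first comparison asked which messages shifted between monosomes and polysomes after thrombin. It used the translation index (TLI), the polysome-to-monosome ratio with thrombin divided by the same ratio in control cells. Among named elements with a signal above the median, the highest TLI, 9.74, belonged to PPP5C, a serine/threonine phosphatase that associates with HSP90. ESR1 (estrogen receptor alpha) followed at 7.98, the membrane-type matrix metalloproteinase MMP15 at 6.43, PIGC, an enzyme of GPI anchor synthesis, at 6.22, and PTPRN, a phosphatase-like protein of secretory granules, at 5.16. The lowest TLI, 0.144, belonged to HIVEP1, a zinc finger protein that binds NF-kappaB-type motifs. SMARCC2, a core subunit of the SWI/SNF chromatin remodelling complex, followed at 0.230, and TAB1, an activator of the kinase TAK1, at 0.266. Within the fixed gene lists, JUNB, an AP-1 transcription factor induced early after stimulation, had a TLI of 2.84, and PRKCA, a protein kinase C, one of 2.59.

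The other higher elements in this named set were the reticulon RTN3 at 3.93, the Mediator subunit MED7 at 3.90, the glucokinase regulator GCKR at 3.83, the RNA-editing enzyme ADAR at 3.15, the splicing cofactor SON at 3.05, the transcription factor MEF2D at 2.88 and OS9, a lectin of endoplasmic reticulum-associated degradation, at 2.84. The other lower elements were the torsin TOR1B at 0.268, the F-box protein FBXW2 at 0.281, SHISA6 at 0.290, GFPT1, the entry enzyme of the hexosamine pathway, at 0.328, and TBL3, a protein of ribosomal RNA processing, at 0.332. These 20 elements lay between 2.43 (TBL3) and 5.97 (PPP5C) times the spread of repeated elements away from the median TLI. SHISA6 was the only gene of the 20 with a further element on the filter, and that element, dimmer than the median, had a TLI of 0.336. Each of the 20 stayed past its limit under quantile normalization and loess. Staying past it under median scaling was part of the rule by which they were chosen, and under a mean without the brightest 1% of elements, which lies between both scalings, it follows from that rule. With a pseudocount of 0.1 of the filter mean, 11 of the 12 higher and 6 of the 8 lower elements did. OS9, TAB1, TOR1B, SHISA6, GFPT1 and TBL3 lay only at the 51.6th to 67.9th signal percentile. Their deposited intensities were 0.632 to 1.96, where the median element has 1, and their distance from background is not known. The signal percentile comes from the mean over the 4 filters, which 1 high value raises. PPP5C (89.6th) had 0.723 to 0.949 on all filters but 1, and HIVEP1 (87.4th) had 1.09 to 1.17. The distance of these low signals from background is not known either.

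In 8 of the 20 elements a single filter lay at least 2.5-fold from each of the other 3, which lay within 2.5-fold of each other. PPP5C had a deposited intensity of 8.31 on the thrombin polysome filter against 0.723 to 0.949 on the other filters, where the median element has 1. HIVEP1 stood at 6.03 on the thrombin monosome filter against 1.09 to 1.17 elsewhere. The thrombin polysome filter also carried the high value of GCKR (9.76 against 1.77 to 2.71) and MED7 (6.25 against 1.29 to 1.99). The control monosome filter carried that of ADAR (24.9 against 5.67 to 9.27), ESR1 (15.0 against 1.16 to 2.07), RTN3 (8.89 against 1.71 to 2.11) and PIGC (5.51 against 1.00 to 1.51). MMP15 differed in both fractions, with a thrombin-to-control ratio of 0.316 in monosomes and 2.03 in polysomes, and so did JUNB, with 0.632 and 1.79. For SMARCC2 the monosome ratio was 3.22 and the polysome ratio 0.741.

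Over all elements, 53 had a TLI of at least 2.5 and 99 a TLI of at most 0.4, the limits given in the design text, with 18 and 30 named elements among them. The split depended on the scaling: upper calls made up 34.9% when each filter was divided by its mean and 65.9% (91 and 47 elements) when it was divided by its median. The median log2 TLI of all elements was -0.18 under the first scaling and 0.07 under the second, so a TLI near 1 has no fixed meaning between them. A simulation in which no element changed, with the spread seen between repeated elements of a gene, put 126 elements past the limits on average (18.6 upper and 108 lower), against 152 observed. With the spread at the lower and upper ends of its 95% interval it put 36.6 and 249 there. For elements of above-median signal the simulation used the smaller spread between their own repeats, from 13 genes (SD 0.48, 95% interval 0.32 to 0.60). It put 20.6 of them past the limits on average, against 94 observed (38 and 56). At the lower and upper ends of that interval it put 0.46 and 75.4 there, and at most 93. These elements were chosen by their observed mean signal, which 1 high value raises, and the simulation did not repeat that choice.

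**Figure D1:**
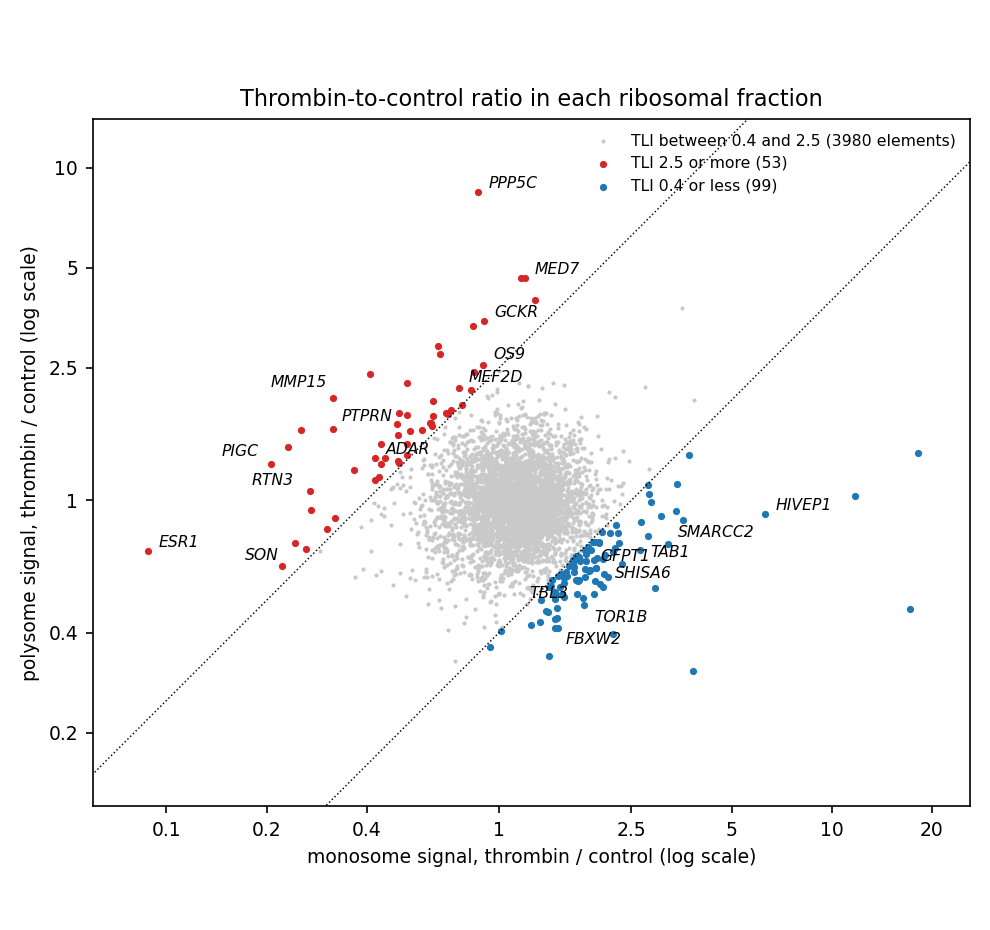
Thrombin-to-control ratio of normalized intensity for each of the 4132 elements, in monosomes on the horizontal and in polysomes on the vertical log axis, with 1 filter per group. Dotted diagonals mark a TLI of 2.5 and 0.4, and names mark the 20 elements named for their TLI, from PPP5C at 9.74 to HIVEP1 at 0.144.

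The gene lists fixed for this tissue and treatment mostly lay within the range of random lists. Of 27 lists, 17 had at least 5 measured genes, and 1 of them, thrombin receptors and G protein signalling, had a median TLI outside the 2.5 to 97.5 percentile range of 10000 random lists matched on signal, where 0.85 lists would fall outside by chance. Its median log2 TLI lay 0.64 above that of all genes, at the 99.7th percentile. Of its 7 measured genes, 5 lay above the median of all genes: PRKCA at 2.59, the G protein subunit GNB1 at 1.45, the regulators of G protein signalling RGS4 at 1.42 and RGS16 at 1.38, and the inositol trisphosphate receptor ITPR1 at 1.27. The receptor kinase GRK2 had 0.776 and ITPR3 0.734. None of the 7 is a thrombin receptor, so the value covers G protein signalling genes only. All members were named because this list stood apart. Only PRKCA passed a TLI limit, and 3 of the 7 had a signal above the median, too few for a value over brighter elements alone.

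The list of immediate-early genes, at the 38.8th percentile, held JUNB and no other member past a limit: of its 14 genes, JUN had a TLI of 1.61, the MAP kinase phosphatase DUSP5 0.631 and KLF4 0.557. The endothelial identity list (82.3rd percentile) had ECE1 at 1.61, CDH5, the cadherin of endothelial junctions, at 1.13, PROCR, the protein C receptor, at 0.826 and FLI1 at 0.757. Translation factors lay at the 20.2nd percentile, with the termination factor ETF1 at 0.597 and an element of EIF1, a factor of start codon selection, at 0.577. The remaining lists spanned the 10.1st percentile (extracellular matrix and integrins) to the 84.6th (RNA splicing). Smooth muscle and fibroblast markers lay at the 37.2nd, which, as a ratio between conditions, does not show whether other cells were present. Across all lists 3 further members passed the lower limit: the chromatin deacetylase HDAC3 at 0.323, the mitotic kinase CDK1 at 0.376 and the death receptor TNFRSF10B at 0.397. They were singled out after their values were seen, and their signals lay below the median. None of 12 genes listed in advance for their link to thrombin or translational control, such as EIF4EBP1, ICAM1 and VWF, had a named element here.

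**Figure D2:**
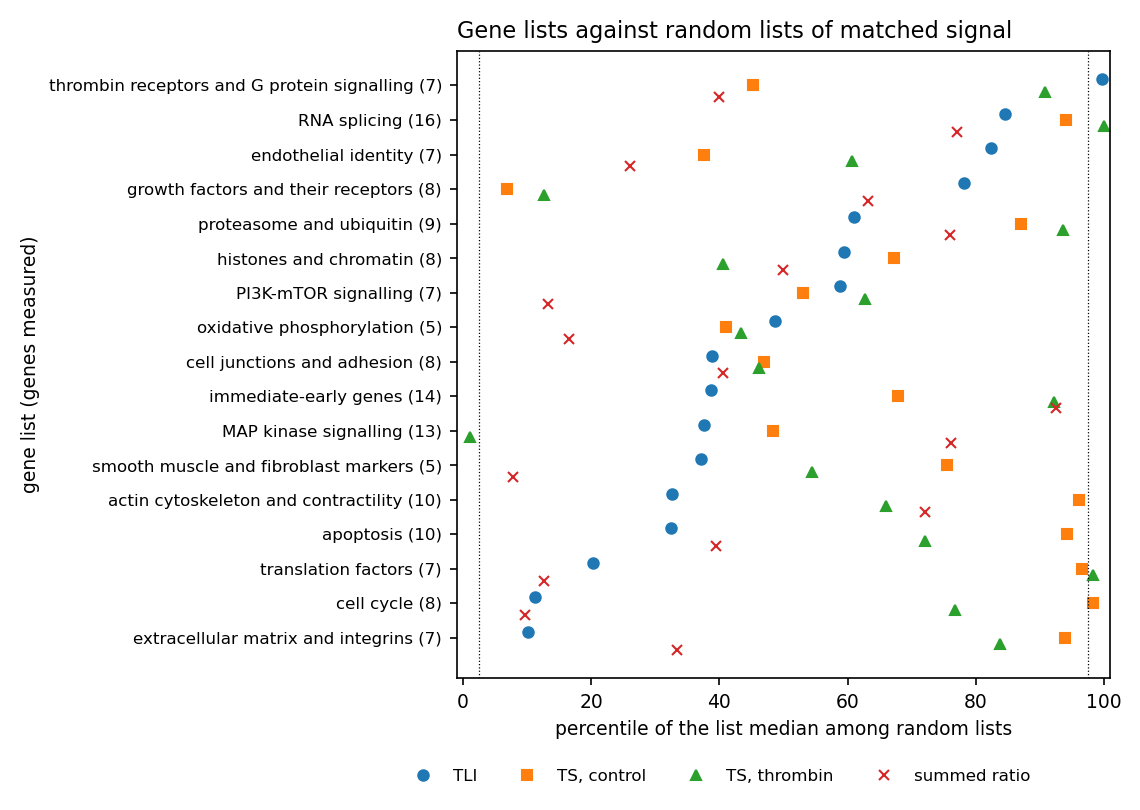
Percentile of the median log2 value of each gene list among random lists of the same size and signal, for the TLI, the translation state (TS) of each condition and the summed ratio, with the number of measured genes in brackets. Dotted lines mark the 2.5 and 97.5 percentiles, and 5 of the 68 points lie outside them.

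The second comparison used the translation state (TS), the polysome signal divided by the monosome signal within a condition. Each filter was divided by its own mean, so a TS is relative to the other elements and gives no share of a message in polysomes. Division by the median multiplies every control TS by 1 constant, which took the higher ACTB value in control cells from 6.09 to 5.10. Cytoskeletal beta-actin was among the messages with the highest TS: the 2 elements of ACTB had a TS of 6.09 and 4.48 in control cells and of 4.97 and 4.51 with thrombin. The spliceosome component SNRPD2 (4.06 and 5.05), the cell cycle kinase CDK6 (4.10 and 3.56), the matrix proteoglycan BGN (3.01 and 3.24) and cytochrome c, CYCS (2.56 and 2.58), were also at or above 2.5 in both conditions. Lactate dehydrogenase, LDHA, had 2 elements in this range, but its other element had a TS of 0.478 and 0.886. That element was far brighter, with a deposited control monosome intensity of 41.9 against 3.22 and 3.58. Whether it reports the same message was not tested. Division by the median lowered the control TS of CYCS to 2.15 and put 1 LDHA element just short of 2.5 with thrombin, and of the 29 elements with a gene name at or above 2.5 in both conditions it left 21 there. At the other end stood SMARCD2, another SWI/SNF subunit, with 0.274 in control cells and 0.242 with thrombin. These genes were chosen after their values were seen.

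A TS of at least 2.5 was found for 222 elements in control cells and 171 with thrombin, and 118 were shared, against 9.19 if the sets were independent. Of these calls, 212 and 168 were elements of above-median signal, while the 9.19 is reckoned over all elements, dim ones included. A TS of at most 0.4 was found for 26 and 15 elements, with 3 shared, of which SMARCD2 was the only named one. Control calls depended on the scaling, with upper calls at 89.5% under division by the mean and 66.7% (138 and 69 elements) under division by the median. The log2 TS of both conditions correlated across elements with a Pearson r of 0.511 (95% bootstrap interval 0.476 to 0.546) and a Spearman rank correlation of 0.411. Across elements of above-median signal the values were 0.624 and 0.607. The interval resamples elements of the same filters, which are not independent replicates, and holds no difference between cultures or filters.

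**Figure D3:**
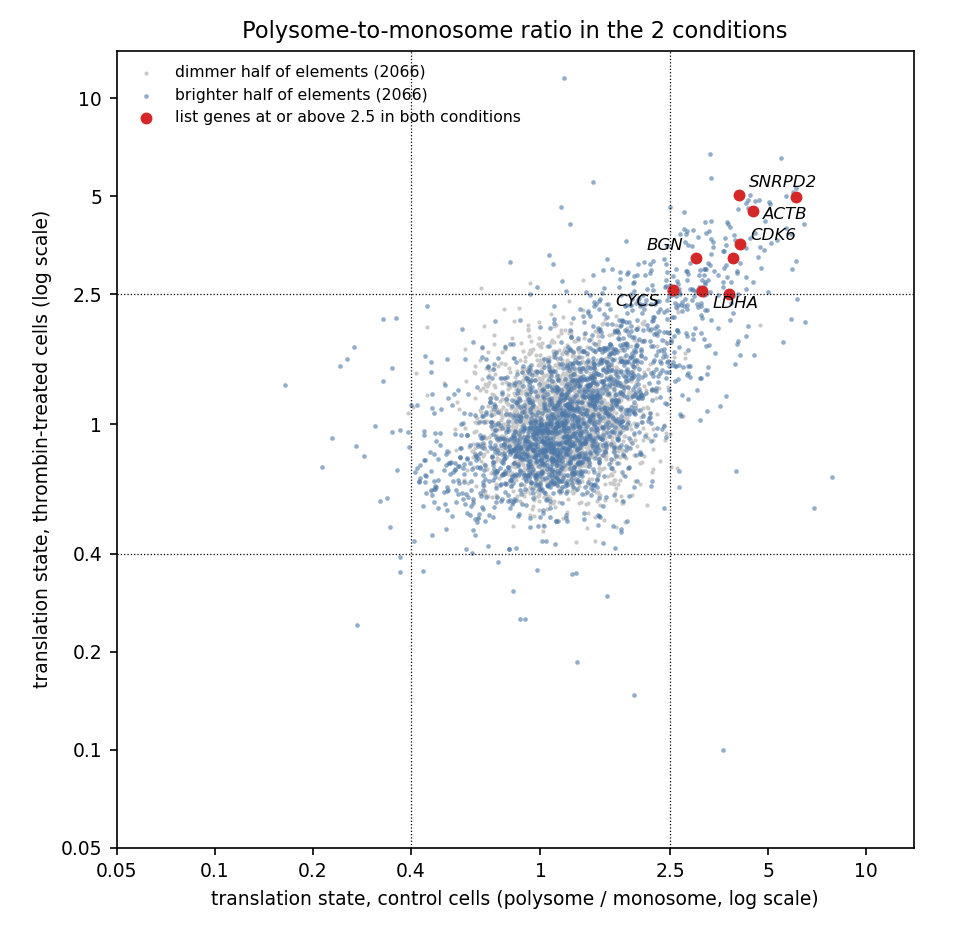
Translation state of each of the 4132 elements in control cells (horizontal) and with thrombin (vertical), both on log axes, with elements of lower signal in grey and of higher signal in blue, 1 filter per fraction and condition. Dotted lines mark 2.5 and 0.4, and red points are the 9 elements of 7 list genes at or above 2.5 in both conditions, with names at those described in the text.

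Over the TLI, both TS and the summed ratio, 5 of 68 list values lay outside the percentile range, against 3.4 by chance. In thrombin-treated cells the RNA splicing list stood highest, with a median log2 TS 0.59 above that of all genes (99.98th percentile, 16 genes, 12 above the median of all genes). SNRPD2 (5.05) was its only member past 2.5, and HNRNPF had 0.961 and SRSF1 0.644. Over brighter elements alone the shift was 0.13, at the 65.8th percentile. Translation factors lay 0.45 above the median of all genes (98.3rd percentile), with 5 of 7 genes above it, among them ETF1 at 1.45, and at the 97.3rd percentile with the brightest element of each gene. MAP kinase signalling lay 0.37 below it (1.08th percentile), with 3 of 13 genes above, among them the stress kinase MAPK10 at 2.08. The stress kinase MAPK8 had 0.471 and its activator MAP2K4 0.424. The MAP kinase list moved to the 7.48th percentile under quantile normalization, the 9.35th under loess and the 5.50th over brighter elements. In control cells the cell cycle list lay 0.40 above the median of all genes (98.3rd percentile, 6 of 8 genes above), with CDK6 at 4.10, and with thrombin at the 76.7th percentile. Its control percentile was 97.2 under quantile normalization and 97.4 under loess. Whether the lists differed between conditions was not tested beyond the TLI percentiles.

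The third comparison used the sum of the monosome and polysome signals with thrombin over the same sum in control cells. The design text relates this measure to transcription. Each filter was divided by its own mean before the sum, so the ratio is relative to the other elements and gives no amount of ribosome-bound message. PPP5C had the highest ratio of the named elements above the median signal, 4.97, followed by HIVEP1 at 3.27 and MED7 at 2.74, and ESR1 had the lowest, 0.176. All of these, PPP5C, HIVEP1, MED7 and ESR1, are elements whose signal deviated on a single filter. The immediate-early genes, the class transcribed within minutes to hours of stimulation, had 11 of 14 members above the median of all genes, with IER2 at 1.59 and the phosphatase DUSP4 at 1.51, both picked after their values were seen, and JUN at 1.15. None of them reached 2.5, and the list lay 0.12 above the median of all genes on the log2 scale, at the 92.4th percentile. The endothelial identity list lay at the 26.1st percentile and smooth muscle and fibroblast markers at the 7.80th, both within the range of random lists.

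Over all elements, 9 had a summed ratio of at least 2.5 and 3 a ratio of at most 0.4. The split was 75% upper calls under division by the mean and 53.3% (8 and 7 elements) under division by the median. The SD of the log2 summed ratio over all elements was 0.31, close to the 0.26 found between elements of the same gene.

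The thrombin-to-control ratio within each fraction showed which filter pair each index came from. In monosomes, HIVEP1 (6.32), SMARCC2 (3.22) and TAB1 (2.66) were higher with thrombin, and ESR1 (0.0883), PIGC (0.207), SON (0.244) and RTN3 (0.270) were lower. In polysomes PPP5C (8.44), MED7 (4.66), GCKR (3.45) and OS9 (2.54) were higher, and the only named element at or below 0.4 was SSX3, a cancer-testis antigen, at 0.363, singled out after its value was seen. Over all elements, 22 were at or above 2.5 and 18 at or below 0.4 in monosomes, and 10 and 5 in polysomes. Division by the median gave 15 and 33 in monosomes (31.2% upper calls against 55%) and 13 and 4 in polysomes (76.5% against 66.7%). Of the 53 elements with a high TLI, 34 had moved more in monosomes, and of the 99 with a low TLI, 57 had. In 39 of the 53 and 77 of the 99 both fractions had moved at least 1.25-fold in opposite directions relative to the median element, which selection by the TLI favours.

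Genes with several elements gave the only repeat measurement. Of 36 such genes with 86 elements, ACTB had TLI values of 0.817 and 1.01, the mitochondrial ribosomal protein MRPL3 had 1.04, 1.11 and 1.11, and SHISA6 had 0.290 and 0.336. Elements of other genes lay far apart: LDHA had 0.661, 0.817 and, for its far brighter element, 1.85, the AAA+ ATPase TRIP13 had 0.529 and 1.61, and the tyrosine kinase SYK had 0.276, 0.864 and 0.873. These genes were chosen after their values were seen. The SD of log2 TLI between elements of the same gene was 0.58 (95% bootstrap interval 0.47 to 0.68), against 0.59 over all elements, and the intraclass correlation was 0.0828, at the 73.9th percentile of random pairings. For the TS with thrombin it was 0.536 and for the TS in control cells 0.357, at the 100th and 99.5th percentiles, and for the mean signal 0.908. For the summed ratio it was -0.0822, for the monosome ratio 0.118 and for the polysome ratio -0.0441, at the 27.55th, 82.4th and 37.95th percentiles. Across brighter elements alone, from 13 genes, it was 0.0452 for the TLI, -0.261 for the summed ratio, 0.469 for the monosome ratio and -0.585 for the polysome ratio. The spread comes from the same hybridisations and holds no difference between cultures. Whether elements with the same gene name report the same message was not tested, so the spread may hold more than noise between spots.

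**Figure D4:**
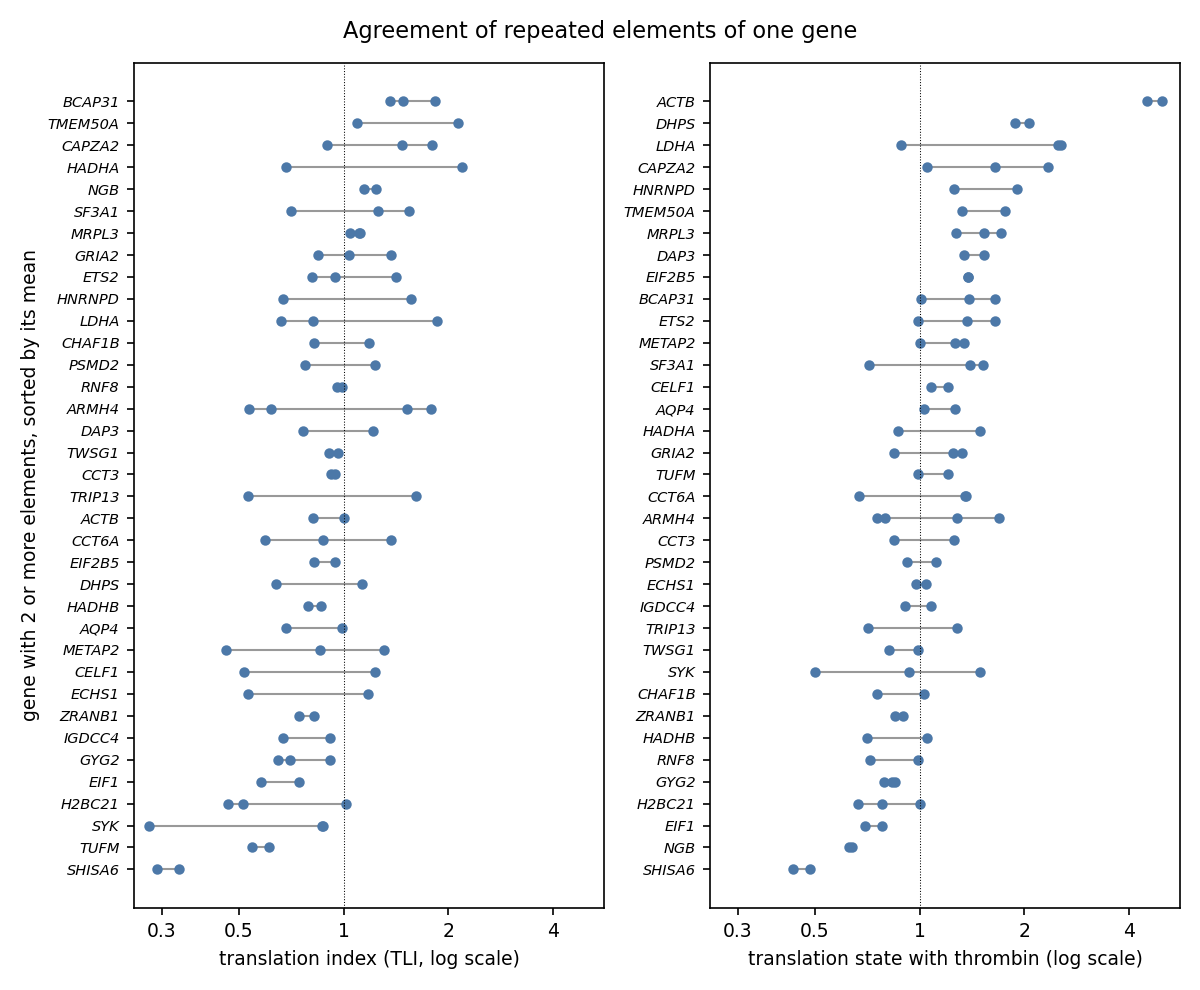
TLI (left) and TS with thrombin (right) of every element of the 36 genes with several elements, on log axes, with a line joining the elements of a gene and genes sorted by their mean. ACTB lies at 4.51 and 4.97 for the TS, above the other genes, while its TLI of 0.817 and 1.01 lies among them.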

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

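The tests of noise among brighter elements, of the split of the simulated calls and of the filter mean were chosen only after the results were seen. For 11 of the 20 elements named for their TLI and for 6 of the elements named from the gene lists, the thrombin-to-control ratio moved in opposite directions in monosomes and polysomes, each by more than the spread of repeated elements, relative to the median element. The difference between the fractions was not tested for any of them, since each fraction and condition had 1 filter, and selection of extreme values of the index, which compares the fractions, favours opposite movement by itself. Of the genes with a higher index, PPP5C (TLI 9.74) had 0.773 in monosomes and 8.63 in polysomes relative to the median element, MMP15 (6.43) had 0.282 and 2.08, PTPRN (5.16) had 0.283 and 1.67, the RNA-editing enzyme ADAR (3.15) had 0.378 and 1.37, and MEF2D (2.88) had 0.673 and 2.22. Of those with a lower index, TAB1 (0.266) had 2.37 and 0.722, TOR1B (0.268) had 1.60 and 0.494, FBXW2 (0.281) had 1.31 and 0.423, SHISA6 (0.290) had 1.85 and 0.614, GFPT1 (0.328) had 1.67 and 0.626, and TBL3 (0.332) had 1.55 and 0.590. From the lists, JUNB (2.84) had 0.563 and 1.83, PRKCA (2.59) had 0.470 and 1.40, the brightest LDHA element (1.85) had 0.705 and 1.50, the histone H2AC6 (1.67) had 0.727 and 1.39, the apoptosis effector BAK1 (0.450) had 1.29 and 0.668, and SDHC (0.504), a subunit of succinate dehydrogenase, had 1.26 and 0.728.

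The elements past the TLI limits were weighed against noise of the size seen between elements of the same gene. The most extreme ones were also weighed against a single deviating spot. Unchanged elements simulated with the repeat spread put 126.17 past the limits on average (18.6 upper and 108 lower) against 152 observed (53 and 99), and with the lower and upper ends of that spread 36.6 (at most 52) and 249 (50.9 and 198), so noise reached the number of calls over part of the interval, but 0 of 21 spreads across it gave both the upper and the lower count. Among elements of above-median signal 94 were past a limit (38 upper and 56 lower) against 20.64 simulated. With the upper end of the spread 75.4 were simulated on average (11.9 and 63.5) and 93 at most. The count, and its upper calls above all, thus lay above the simulated noise. But the noise was assumed normal in both simulations, here with a spread from 13 genes, and every element was given the same shift and spread. The brighter elements were also chosen by their observed mean over the same 4 filters, which 1 high value raises. The simulation kept that set and did not choose again after noise was added, so the observed and simulated counts are not fully alike. In the data the median log2 TLI under median scaling was -0.01 at the 50th to 75th signal percentile and 0.41 above the 97th. Its SD was 0.55 in the first of these groups and 0.69 in the second. The simulations held no such trend with signal and cannot decide, so noise stays open for all calls. Of the 14 elements more than 4 repeat SDs from the median TLI, 7 (PPP5C, ESR1, PIGC and HIVEP1 among them) had 1 filter at least 2.5-fold from each of the other 3, which lay within 2.5-fold of each other, and 10 had both fractions moved at least 1.25-fold in opposite directions, with 3 (PPP5C, PIGC and an unnamed one) counting under both. For the 7 a deviating spot and a true change cannot be told apart, since every fraction was measured once, and a response to thrombin stays open and untested for all of the elements.

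The surplus of lower over upper TLI calls may come from the brightest elements setting the filter mean. Leaving the brightest 1% out of the mean raised the share of upper calls from 34.9% to 45.9% (62 and 73 elements), and division by the median raised it to 65.9% (91 and 47). Both multiply every TLI by 1 constant (1.06 and 1.19), so the shift of the share follows from the filter means alone, and a scaling effect and a true lean to lower values cannot be told apart. With the filter means kept, limits of 4 and 0.25 gave 12 upper and 10 lower calls, so the direction of the surplus depended on both the scaling and the limits. No biological explanation for it was tested.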

How the results depend on the processing

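The mean without the brightest 1% was chosen only after the data were seen. Counts are given as upper and lower calls in the order TLI, TS control, TS thrombin, summed, monosome and polysome ratio; the cause of each shift was not tested unless the setting itself sets it. Limits of 2 and 0.5 gave 110 and 248, 408 and 76, 303 and 46, 17 and 16, 65 and 44, and 32 and 33; limits of 4 and 0.25 gave 12 and 10, 54 and 4, 31 and 4, 3 and 1, 4 and 5, and 3 and 0, both by construction. Median scaling moved the TLI to 91 and 47, TS control to 138 and 69, lower summed calls to 7 and lower monosome calls to 33. Quantile normalization gave 78 and 60 for the TLI, 96 and 71 for TS control, 87 and 43 for TS thrombin, 8 lower summed, 30 lower monosome and 3 lower polysome calls. Loess gave 79 and 56 for the TLI, 109 and 56 for TS control, 100 and 24 for TS thrombin and 7 lower summed calls. The mean without the brightest 1% gave 137 and 70 for TS control, 29 lower TS thrombin and 7 lower summed calls. A pseudocount of 0.1 gave 32 and 40 for the TLI, 14 upper monosome and 3 lower polysome calls. Brighter elements alone, fewer by construction, gave 56 lower TLI calls and a shift of the RNA splicing list of 0.13 for TS thrombin. The list of thrombin receptors and G protein signalling and the cell cycle list had too few bright genes for a value. The surplus of lower TLI calls thus turned around under median scaling, quantile normalization, loess and the limits of 4 and 0.25. The remaining 88 alternative values of these results, the 78 and 79 upper TLI calls among them, stayed within 1.5 times the count or within the spread of random lists, and no list shift among them changed sign. Of the values for single genes and other lists 562 stayed and 15 moved. Of 427 alternative values of lists inside the 2.5th to 97.5th percentiles of random lists, 5 lay outside. Growth factors and their receptors in TS control fell to the 0.87th percentile (shift -0.61) under quantile normalization and the 0.52nd (-0.64) under loess. Translation factors lay at the 2.1st percentile (-0.24) for the summed ratio with the brightest element of each gene, and at the 98.9th (0.52) for TS control over brighter elements, where proteasome and ubiquitin lay at the 98.2nd (0.70). No analysis paired by replicate was possible because each group had 1 filter, and leaving out a replicate was not possible for the same reason. Signal over background, which limits dim elements, was not used here.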

Other observations

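The tests of a faulty filter and of opposite movement of the fractions were chosen only after the result was seen. The brightest elements leaned to monosomes, unlike the beta-actin message. Among the brightest named elements, all chosen after their values were seen, the inositol phosphatase INPP5J had a TS of 0.546 in control cells and 0.729 with thrombin, MALL had 0.613 and 0.561, the actin-binding caldesmon CALD1 had 0.597 and 0.782, the basement membrane protein NID1 had 0.505 and 0.617, and the lipid kinase subunit PIK3CD had 0.472 and 0.630. Both elements of neuroglobin, NGB, lay close together, at 0.517 and 0.551 in control cells and at 0.640 and 0.629 with thrombin. Beta-actin, in the same signal range, had 4.48 to 6.09 in control cells.

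Of the 124 elements in the brightest 3%, 74.2% lay below a TS of 1 in control cells and 66.1% with thrombin under median scaling, so a fault of 1 filter cannot account for the lean. A candidate explanation is that 1 abundant RNA species hybridised to many elements. The 88 elements with a control TS below 0.8 had a median TS of 0.570 in control cells and 0.672 with thrombin under division by the mean, and the SD of their log2 TS with thrombin was 0.457, against 0.418 between repeated elements and 1.07 among the 32 brightest elements with a control TS of 1 or more. That spread is narrower than that of the polysome-leaning elements but above the repeat spread, which keeps the explanation open. No biological explanation was tested.

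Lower monosome signal paired with higher polysome signal of the same message would suggest a movement of message between the fractions. Across the brighter elements the log2 thrombin ratios of monosomes and polysomes had a Pearson r of 0.0332 (95% interval from resampled elements -0.02 to 0.09). This value decides nothing, since shared and opposite movements of equal size also give a value near 0. Of the brighter elements, 24 of the 38 with a high TLI and 43 of the 56 with a low TLI had both fractions moved at least 1.25-fold in opposite directions relative to the median element, but these were selected by the TLI itself. With the polysome ratios shuffled over the brighter elements, 45.3% of high and 55.4% of low calls did so on average (central 95% of shuffles 30% to 60% and 44% to 66.3%), against 63.2% and 76.8% observed, though shuffling also breaks any tie between the sizes of both movements. How far opposite movement made up the spread of the TLI stays open.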
